A study of Homo sapiens with 28 samples.

How the data were processed

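RNA of human pluripotent cell lines was measured on Affymetrix Human Exon 1.0 ST arrays, in 14 arrays summarised at 2 levels. Embryonic stem (ES) cell lines are derived from embryos, and embryonal carcinoma (EC) cell lines from germ cell tumours. Per the labels, all cells were sorted for the surface antigen SSEA3. The ES lines H14, Shef5, Shef6, Shef3, H9 and Shef7 (replicates 1 to 6, n = 6) grew on inactivated mouse embryo fibroblasts (feeders), in knock-out medium with serum replacement and FGF. The EC lines NCCIT, 2102Ep, 833KE, TERA1 and NTERA2 (replicates 1 to 5, n = 5) grew on plastic in medium with fetal calf serum. The EC lines NTERA2, 2102Ep and 833KE (replicates 1 to 3, n = 3) were also grown on feeders in the ES medium. Each array is a different cell line or growth condition, so the replicates of a group are lines and not repeats of 1 culture.

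The deposited gene-level values are log2 values, 1 for each of 22011 transcript clusters. The deposited exon-level values are log2 values, 1 for each of 287329 probesets. The authors' labels name RMA, Affymetrix Expression Console and limma, without versions, RMA settings, log base or annotation release; the log2 scale was read from the range of the values. The array medians of the deposited values lay between 6.19 and 6.39 at gene level, so these summaries were not quantile normalised as they stand. Detection p-values were not used here, so the signal over background of a single value is unknown, and the number of arrays limits the precision. Genome positions were not used here, and chromosomes come from matching gene symbols to a human RefSeq annotation, which also set the gene order on chromosome 12.

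Symbols came from the annotation of the platforms. At gene level 14432 clusters had 1 symbol, 2408 had several and 5171 had none, which left 14220 distinct genes. At exon level 261273 probesets had 1 symbol. POU5F1, NANOG and SOX2 had no cluster with 1 symbol and were read from their probesets. All deposited columns were used. Nothing was transformed, filtered or renormalised before the fits unless stated.

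Comparisons used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all features and a threshold of 0.05 on the adjusted p. Figures were drawn with matplotlib 3.10.9. EC lines on plastic (n = 5) were compared with ES lines (n = 6), where cell type and growth condition differ together. EC lines on feeders (n = 3) were compared with ES lines (n = 6) under the same growth condition. EC lines on feeders were compared with the same 3 lines on plastic, with the line as a block. Pairing was checked after removing each condition's mean. The correlation across genes of a feeder array with the plastic array of its own line was 0.41 for 2102Ep, 0.34 for 833KE and 0.51 for NTERA2. It was below 0 with every other line, which is partly built in. Removing the mean makes the deviations of the 3 lines sum to 0, so a positive value with the own line pulls the others down.

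The 23 gene lists were pluripotency factors, germline genes, cancer-testis antigens, endoderm, mesoderm, neural and ectoderm, and trophoblast markers, fibroblast and extracellular matrix genes, blood and endothelial markers, imprinted genes, DNA methylation genes, p53 targets, sterol and fatty acid synthesis, FGF and ERK response, nodal and activin pathway, WNT pathway, interferon response and antigen presentation, cell cycle, metallothioneins and metal response, hypoxia and glycolysis, oncogenes of germ cell tumours, regulators of splicing, and genes of the short arm of chromosome 12 (12p). Each list was tested with camera (preset correlation 0.01), adjusted over the lists, with camera's estimated correlation and fry beside it. The same test was run on chromosomes. Exon usage was tested with limma's diffSplice on probesets above the 25th percentile in both groups, in genes above the median in both groups with at least 3 kept probesets, with a difference of at least 1 on the log2 scale from the gene's other probesets.

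Genes are named by a rule. For EC on plastic against ES these are the 12 highest and 12 lowest differences among called genes whose groups did not overlap, and 6 each way for EC on feeders against ES. For feeders against plastic, where no gene was called, they are the 6 smallest p each way. Each list gives up to 4 called members, or the 2 with the smallest p. For exon usage they are the 10 largest differences, 1 per gene. Comparisons, lists, this rule and most alternatives were set before the data were examined. Chosen after seeing the data were all alternatives that use the array codes in the labels, the tests of RNA of the mouse feeder cells and of probesets that do not follow their gene, the counts of splits for single lists, the division of chromosome 12 genes by signal, the values of ZNF genes and of chromosome 13, and the genes whose single probeset changed. Codes up to 13 are called earlier (4 arrays) and codes from 17 later (10 arrays); the labels do not say what the codes stand for.

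The fits were tested on simulated data with 200 changed clusters among 22011. EC on plastic against ES recovered 56% of 2-fold and 94% of 4-fold changes with 10 false calls. EC on feeders against ES recovered 39% and 89% with 7 false calls, and the paired fit 29% and 98% with 12. For the paired fit the simulated noise was the spread within lines; a first version that used the spread between lines recovered none and was replaced. A shifted list was found in each fit with 0 other lists called. The simulated noise was independent between genes, so this says little about false calls of lists whose members vary together. The exon usage fit recovered 85% of 200 changed probesets with 26 false calls.

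Alternatives were quantile normalisation, equal array medians, a filter on dim features, another prior, clusters with 1 symbol, other choices of arrays, other exon usage filters, a splicing index, leaving out each array, and the array codes.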

Results

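Gene expression was compared between tumour-derived EC lines and ES lines, which share the pluripotent state, at the level of genes and of exon probesets. The 14 arrays comprised 6 ES lines on feeders, 5 EC lines on plastic and 3 of these EC lines on feeders. Pairs of arrays correlated across genes with r from 0.931 to 0.984. The first principal component held 23.7% of the variance. All 6 ES lines scored from -50.5 to -10.5 on it, and the EC lines 2102Ep and 833KE in both growth conditions and TERA1 on plastic from 32.7 to 45.8. The other 2 EC lines scored lower than these, with NTERA2 at -1.17 on plastic and 14.1 on feeders and NCCIT at -22.7. The second component held 17.3%. The 4 arrays with earlier codes (ES lines H14 and Shef5, and NTERA2 and 2102Ep on feeders) scored from -46.4 to -29.0 on it, and the 10 others from -5.82 to 68.0. Because the codes split arrays within 2 of the groups, counts of genes that allow for the codes are also given for both EC-ES comparisons.

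**Figure D1:**
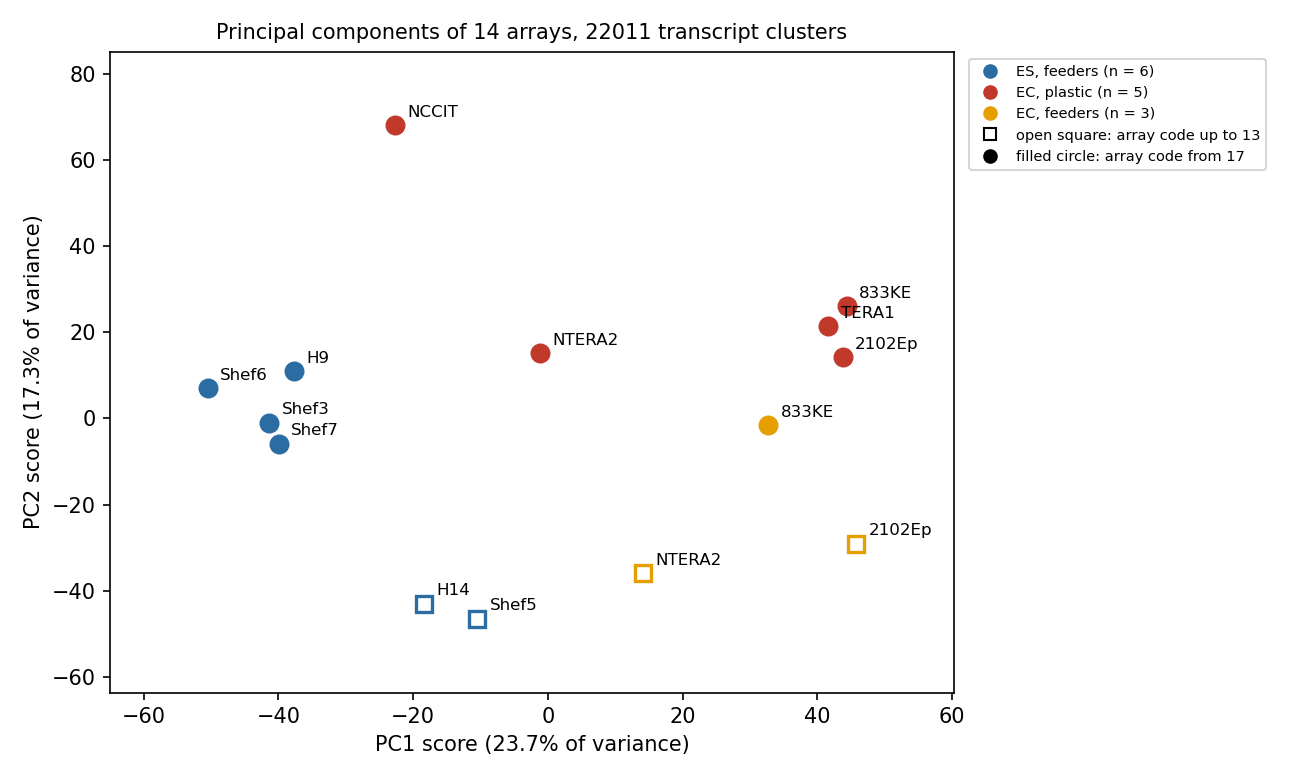
Scores of the 14 arrays on the first (x axis) and second (y axis) principal component of the gene-level log2 values, coloured by group. Open squares, the 4 arrays with earlier codes, lie at -29.0 or below on the second component, and filled circles, the later codes, at -5.82 or above.

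The first comparison asked which genes separate EC lines on plastic from ES lines. Among called genes whose groups did not overlap, the largest loss was in CER1, a secreted antagonist of nodal and BMP signals (transcript cluster 3199500), at 4.82 ± 0.52 in EC (SD, n = 5) against 10.12 ± 0.55 in ES (SD, n = 6), which is 39.6-fold lower (log2 difference -5.31, SE 0.30, adjusted p = 1.08e-05). ACTC1, cardiac actin, differed by -3.96 and TRPC4, a cation channel, by -3.20. IDO1, an enzyme of tryptophan breakdown, differed by -3.11, PMEL, a melanosome matrix protein, by -3.09, and CYP26A1, which degrades retinoic acid, by -2.87. FST, an activin antagonist (-2.77), LGR5, a receptor for R-spondins (-2.31), and MIXL1, a transcription factor of the primitive streak (-2.25), also fell, as did GPR176 (-2.94), VAT1L (-2.78) and ADAMTS19 (-2.69). The largest gain among them was in the zinc finger gene ZNF208 (cluster 3856646), at 9.92 ± 1.88 in EC (SD, n = 5) against 4.75 ± 1.00 in ES (SD, n = 6), 36.0-fold higher (log2 difference 5.17, SE 0.77, adjusted p = 0.00464). The zinc finger genes ZNF560 (3.96), ZNF99 (3.69) and ZNF680 (3.07) rose as well. HORMAD1, a protein of meiotic chromosome axes, rose by 3.84, CLEC4D by 3.56, GDF3, a TGF-beta family ligand, by 3.49 and LINC00189 by 3.29. The DNA sensors IFI16 and CGAS rose by 3.05 and 2.92, and ZYG11A and TRIML2 by 2.76 each.

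With limma, 718 clusters were higher and 294 lower in EC on plastic (1012 of 22011), of which 406 and 159 differed by at least 2-fold. Among the later-coded arrays 376 were higher and 151 lower, of which 458 in all were also called with all arrays, and with the code as a block 537 and 229. Quantile normalisation gave 571 higher and 437 lower. Without Shef3, 2102Ep, Shef7, Shef6, H14 or 833KE the total was 587, 604, 618, 634, 656 and 658. Of the 24 genes named above, CLEC4D (difference 3.55, adjusted p = 0.0778) and ZNF680 (3.10, adjusted p = 0.0565) were not called among later-coded arrays. There CER1 differed by -5.23 and ZNF208 by 4.81. The call of CLEC4D was also lost without 833KE (adjusted p = 0.0507), and that of MIXL1 without Shef6 (0.0584), 2102Ep (0.0534) or TERA1 (0.0549). With the 3 lines also grown on feeders, ZNF680 (0.0794) and MIXL1 (0.0916) were not called, nor was MIXL1 with EC arrays of both growth conditions (0.268) or the spread of all 14 arrays (0.102).

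**Figure D2:**
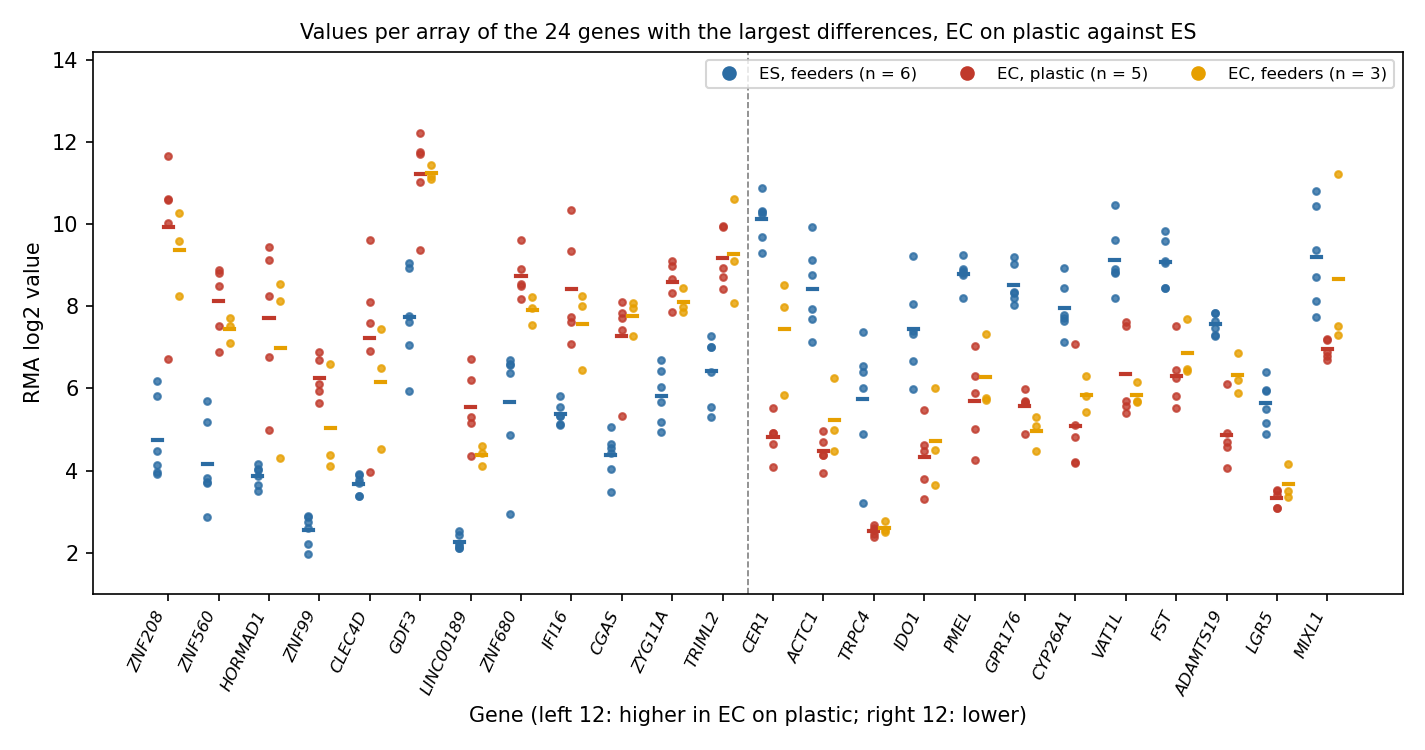
RMA log2 value (y axis) of the 24 genes named by rule (x axis) in each array, with bars at the group means; CER1 was 4.82 in EC on plastic and 10.12 in ES. EC arrays on feeders are shown beside them and did not enter the choice of the genes.

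Pluripotency genes rose in EC on plastic in 5 of 25 measured members (9 up and 1 down adjusted over the list alone; median 0.40, adjusted p = 0.0106; adjusted p = 0.370 with an estimated correlation). They included GDF3, NR5A2, an orphan nuclear receptor (2.39), and TFCP2L1 (2.31) and KLF4 (1.74), transcription factors of the naive pluripotency network. The list's call was lost without 833KE (adjusted p = 0.0527). At their own probesets, 1 of 2 NANOG probesets was higher (2.04, adjusted p = 0.0465) and the other differed by 1.44 (adjusted p = 0.0629). NANOG and GDF3 are also on the 12p list, whose measured genes rose by a median of 1.10 (below). None of 4 POU5F1 and 6 SOX2 probesets was called by limma, with smallest adjusted p of 0.446 and 0.764. In EC on plastic the POU5F1 probesets lay at 8.95, 6.59, 3.66 and 3.64, against exon-level array medians of 6.55 to 6.76. The 2 dimmest lay far below these medians and may show little, so the missing calls do not show POU5F1 unchanged. The brightest was higher than in ES (8.32) by 0.63 on plastic, and was at 9.58 in EC on feeders.

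Endoderm markers fell together, with 4 of 18 members lower and none higher (8 down adjusted over the list alone; median -0.68, adjusted p = 3.99e-09; adjusted p = 0.0598 with an estimated correlation). Besides CER1 these were the transcription factors EOMES (-1.79), GATA6 (-0.77) and SOX17 (-0.65); SOX17 lost its call among later-coded arrays (adjusted p = 0.0824), with the code as a block (0.0672) and without any 1 of 4 arrays. Mesoderm markers fell in 2 of 16 (3 down adjusted over the list alone; median -0.25, adjusted p = 0.00600; adjusted p = 0.347 with an estimated correlation), namely MIXL1 and the cadherin CDH11 (-1.11). Neural markers fell in 1 of 19 (1 adjusted over the list alone; median -0.25, adjusted p = 0.00931; adjusted p = 0.282 with an estimated correlation), the transcription factor ZIC2 (-1.29). With fry the mesoderm (adjusted p = 0.0791) and neural (0.0990) calls were lost. CDH11 lost its call among later-coded arrays (adjusted p = 0.0638) and without any 1 of 7 arrays, and ZIC2 among later-coded arrays (0.0502) and without any 1 of 6. Germline genes rose in 2 and fell in 1 of 24 (3 up and 1 down adjusted over the list alone; median 0.17, adjusted p = 0.0327; adjusted p = 0.109 with an estimated correlation), with TDRD5, a factor of the piRNA pathway, at 2.54 and TFAP2C at 1.19. The germline call was lost among later-coded arrays (adjusted p = 0.0897), with the code as a block (0.0770), with the 3 lines also grown on feeders (0.0542) and without Shef5 (0.0600), NCCIT (0.0738) or H9 (0.0861). With dim clusters left out its median was -0.056 (adjusted p = 0.824).

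Fibroblast and extracellular matrix genes were lower in EC on plastic in 5 of 31 members (16 down adjusted over the list alone; median -0.47, adjusted p = 1.03e-07; adjusted p = 0.175 with an estimated correlation), among them the collagen genes COL1A1 (-1.65), COL5A2 (-1.40) and COL6A1 (-1.32) and the matrix-associated protein CCN2 (-1.36). CCN2 was not called among later-coded arrays (adjusted p = 0.0525), COL1A1 with the 3 lines also grown on feeders (0.0739) and COL6A1 with EC arrays of both growth conditions (0.139). The ES lines grew on mouse fibroblasts and these EC arrays did not; the same list had a median difference of 0.51 between feeders and plastic in 3 EC lines. WNT pathway genes fell in 7 of 29 and rose in 1 (11 down and 2 up adjusted over the list alone; median -0.37, adjusted p = 1.90e-05; adjusted p = 0.109 with an estimated correlation). Among those that fell, SFRP1 (-3.24) and DKK1 (-2.07) are secreted WNT antagonists, LGR5 (-2.31) a receptor and LEF1 (-1.57) a transcription factor of the pathway. LEF1 was not called among later-coded arrays (adjusted p = 0.0852), DKK1 and LEF1 were not called with the code as a block, and SFRP1, DKK1 and LEF1 were not called with the 3 lines also grown on feeders. FGF and ERK response genes rose in 5 of 22 (7 adjusted over the list alone; median 0.52, adjusted p = 0.00488; adjusted p = 0.241 with an estimated correlation), with the transcription factors ETV5 (2.49) and ETV1 (1.54) and the feedback inhibitors SPRY4 (1.54) and SPRY2 (1.10). ETV1 lost its call among later-coded arrays (adjusted p = 0.139), with the code as a block (0.0982) and without any 1 of 7 arrays; SPRY4 lost it without any 1 of 9 and SPRY2 of 3. Sterol and fatty acid synthesis genes rose in 5 and fell in 1 of 25 (10 up and 1 down adjusted over the list alone; median 0.45, adjusted p = 6.40e-05; adjusted p = 0.0598 with an estimated correlation). FDPS of the mevalonate pathway rose by 1.05 and ACSS2, which makes acetyl-CoA, by 0.94, and TM7SF2, a sterol reductase, fell (-0.84). SC5D (0.92) lost its call among later-coded arrays (adjusted p = 0.112), with the code as a block (0.0753) and without any 1 of 8 arrays.

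Besides these 9 lists and the 12p list, 13 lists did not pass in EC on plastic against ES. Nodal and activin genes had an adjusted p of 0.0922 with 1 member higher (GDF3) and 2 lower (CER1 and FST), hypoxia and glycolysis genes 0.104, cell cycle genes 0.142, p53 targets 0.297, and regulators of splicing 0.396. Interferon and antigen presentation genes, metallothioneins and oncogenes each had 0.709, blood and endothelial markers 0.71, imprinted genes 0.822, cancer-testis antigens and DNA methylation genes 0.836 each, and trophoblast markers 0.961. The median and the mean differed in sign for regulators of splicing (0.024 and -0.11) and trophoblast markers (-0.043 and 0.10). Single members passed all the same, among them BNIP3, a hypoxia target (1.69), the cell cycle genes FOXM1 (1.15) and CENPA (0.89), the cyclin CCND2 (1.47), the growth factor receptor ERBB2 (-1.77) and FTL, the ferritin light chain (-2.17). FOXM1 and CCND2 are also on the 12p list, which rose as a group. CCND2 (adjusted p = 0.0733) and CENPA (0.0581) were not called among later-coded arrays, nor CCND2 with the code as a block (0.0679). In all, 10 of 23 lists passed with camera's preset correlation, 0 with an estimated correlation and 9 with fry, which called nodal and activin genes (adjusted p = 0.00375) and not the mesoderm and neural markers.

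Genes of the short arm of chromosome 12, which germ cell tumours often carry in extra copies, were higher in EC on plastic in 55 of 102 measured members and lower in none (70 up and 1 down adjusted over the list alone; median 1.10, adjusted p = 4.69e-29; adjusted p = 0.0598 with an estimated correlation). GDF3 (3.49), PLBD1 (2.36), EPS8 (2.11) and RASSF8 (2.10) had the largest differences; PLBD1 lost its call among later-coded arrays (adjusted p = 0.0503) and without any 1 of 5 arrays. Among later-coded arrays the median was 1.06. Over the 65 brighter genes of the list, relative to the median of all brighter genes of each array, each EC array exceeded the ES lines, with medians of 1.68 in 2102Ep, 1.54 in TERA1, 1.29 in NTERA2, 1.25 in 833KE and 0.56 in NCCIT on plastic, and 1.51, 1.36 and 0.90 in 2102Ep, 833KE and NTERA2 on feeders; the ES lines lay between -0.17 and 0.13. The 115 genes of 12p that were not on the list had a median of 0.48, with 29 higher and 0 lower by limma (unadjusted camera p = 2.20e-14, and 0.0286 with an estimated correlation). The 567 genes of the long arm had a median of 0.056, with 19 higher and 10 lower, and camera gave an unadjusted p of 0.311. By whole chromosome, camera called 1, 12 and X as higher and 14, 16, 19 and 22 as lower with medians from -0.13 to 0.14, and none with an estimated correlation, where the smallest adjusted p was 0.610. Chromosome 16 was higher instead in EC on feeders against ES (median 0.14, against -0.092). The chromosome tests did not allow for the codes. Measured over brighter genes as above, H14 and Shef5 (earlier codes) were at 0.14 and 0.17 on chromosome 16. They were at 0.14 and 0.27 on chromosome 19. The later-coded ES lines ran from -0.26 to 0.023 and from -0.28 to -0.011 there. EC on plastic, all later-coded, ran from -0.33 to 0.037 and from -0.45 to -0.047. On chromosome 22 the later-coded ES lines ran from -0.25 to 0.041 and EC on plastic from -0.33 to -0.22.

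**Figure D3:**
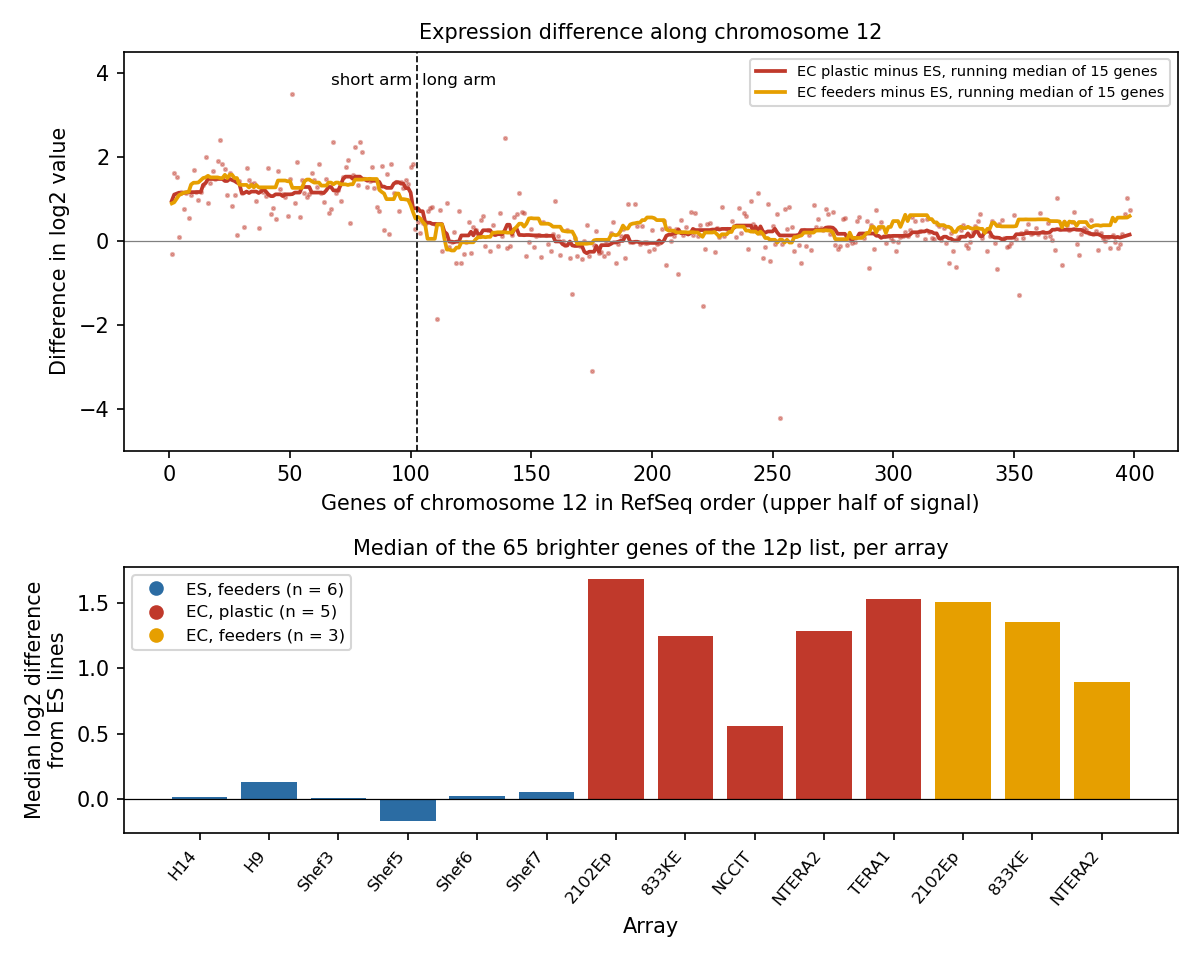
Top, log2 difference between EC and ES (y axis) of the brighter genes of chromosome 12 in their order (x axis), with points for EC on plastic and lines for running medians of 15 genes. Bottom, median log2 difference from the ES lines (y axis) of the 65 brighter listed 12p genes in each array (x axis), from 0.56 in NCCIT to 1.68 in 2102Ep among EC arrays on plastic.

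The second comparison set EC against ES lines with both on feeders. ZNF208 was again the largest gain, at 9.36 ± 1.03 in EC (SD, n = 3) against 4.75 ± 1.00 in ES (SD, n = 6), 24.5-fold higher (log2 difference 4.62, SE 0.60, adjusted p = 0.00637). The metallothionein pseudogene MT1L rose by 3.93, SPP1, which encodes osteopontin, by 3.67, IL20RB, a cytokine receptor chain, by 3.60, NRK, a kinase, by 3.57 and ABCG2, a drug efflux transporter, by 3.51. GPR176, at 4.96 ± 0.43 in EC (SD, n = 3) against 8.52 ± 0.47 in ES (SD, n = 6), had the largest loss (log2 difference -3.56, SE 0.29, adjusted p = 8.88e-04). VAT1L (-3.30), SFRP1 (-3.27), ACTC1 (-3.19) and MGAT4C (-3.04) fell too, as did OTX2 (-3.10), a transcription factor of the primed pluripotent state and forebrain. CER1 was lower here by a smaller amount (-2.68, adjusted p = 0.0327).

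With limma, 343 clusters were higher and 161 lower in EC on feeders (504 of 22011), of which 271 and 129 differed by at least 2-fold. With the code as a block 279 were higher and 129 lower. Among later-coded arrays, where EC has 1 array assumed to vary like the ES lines, 186 and 181 were called. Among earlier-coded arrays (2 against 2) limma called 0, with 2366 at an unadjusted p below 0.05 against 3875 with all arrays. The total fell to 167, 193, 235 and 260 without Shef3, 2102Ep, Shef6 or Shef7. Of the 12 genes named above, ZNF208, MT1L, SPP1, ABCG2, GPR176 and VAT1L were called whichever array was left out. MT1L and NRK were not called with the spread of all 14 arrays (adjusted p = 0.108 and 0.0973). Among later-coded arrays ACTC1 (adjusted p = 0.0644) and MGAT4C (0.0690) were not called, and among earlier-coded arrays none of the 12 was called by limma. The differences among earlier- and later-coded arrays were 2.23 and 5.66 for MT1L, 2.34 and 5.80 for IL20RB, 2.67 and 4.09 for SPP1, 2.78 and 4.62 for NRK, -1.94 and -4.40 for SFRP1, -1.84 and -4.07 for OTX2, -1.86 and -3.53 for MGAT4C and -2.03 and -4.22 for CER1. In the same order ZNF208 differed by 4.89 and 5.15 and ABCG2 by 2.82 and 3.99. GPR176 differed by -2.92 and -4.24 and VAT1L by -2.58 and -3.78. Of these genes only ACTC1 had the larger difference among earlier-coded arrays (-4.16 and -2.89). With the code as a block all 12 and CER1 were called. IL20RB lost its call without any 1 of 7 arrays, MGAT4C of 6, ACTC1 and SFRP1 of 2, and NRK and OTX2 of 1; CER1 lost it without any 1 of 5.

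By list, 12p genes rose again, with 41 of 102 higher and 1 lower (74 up and 2 down adjusted over the list alone; median 1.07, adjusted p = 5.88e-29; adjusted p = 0.0643 with an estimated correlation). They included PLBD1 (3.04) and the cyclin CCND2 (1.96). Endoderm markers fell in 2 of 18, CER1 and the chemokine receptor CXCR4 (-1.33; 4 down adjusted over the list alone; median -0.51, adjusted p = 5.09e-06; adjusted p = 0.229 with an estimated correlation). CXCR4 lost its call with the code as a block (adjusted p = 0.0562) and without any 1 of 6 arrays. Neural markers were lower as a list (median -0.20, adjusted p = 0.00384; adjusted p = 0.357 with an estimated correlation), while limma called 0 of 19 members (0 adjusted over the list alone; DCX, with the smallest p, differed by -1.12, adjusted p = 0.0781). Regulators of splicing were lower as a list (median -0.12, adjusted p = 0.0144; adjusted p = 0.263 with an estimated correlation), while limma called 0 of 27 members (2 down adjusted over the list alone; NOVA1 differed by -0.84, adjusted p = 0.0643, and CELF2 by -0.86, adjusted p = 0.0672). That call was lost among earlier-coded arrays (median 0.042, adjusted p = 0.156). Germline genes rose in 3 and fell in 2 of 24 (7 up and 2 down adjusted over the list alone; median 0.28, adjusted p = 0.0439; adjusted p = 0.229 with an estimated correlation). TDRD5 rose by 1.99 and PIWIL1, of the piRNA pathway, by 1.45, while the receptor KIT fell (-1.90). The germline call was lost with equal array medians (adjusted p = 0.0666), with the spread of all 14 arrays (0.0527), among earlier-coded arrays (0.301) and without H14 (0.0596), Shef5 (0.0947), H9 (0.0745) or 833KE (0.225), and the list's median was -0.076 with dim clusters left out (adjusted p = 0.605). The 18 other lists did not pass. Among lists that had passed in EC on plastic, WNT genes had a median of -0.11 (camera adjusted p = 0.0566). FGF and ERK response genes had 0.36 (0.0948). Pluripotency genes had 0.25, sterol and fatty acid synthesis genes 0.28 and mesoderm markers -0.15 (0.266 each). Fibroblast and extracellular matrix genes had a median of -0.12 (adjusted p = 0.221) with 0 of 31 called by limma. With the same 3 lines on plastic, 9 of the 10 lists called there still passed, all but germline genes. The cause of the lost calls was not tested. The median and the direction of the test differed for cancer-testis antigens (0.066, lower) and oncogenes (0.20, lower), and the median and mean for imprinted genes (0.069 and -0.015). In all, 5 of 23 lists passed with the preset correlation, 0 with an estimated correlation and 2 with fry (12p and germline genes); fry did not call endoderm markers (adjusted p = 0.0807), neural markers (0.140) or regulators of splicing (0.140).

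The EC-ES differences of both growth conditions shared genes. Of the genes higher in EC, 173 were called in both comparisons, and 74 of those lower, where independent lists of these sizes would share 11.2 and 2.15; the ES lines and 3 EC lines are common to both comparisons, so the lists are not independent. The differences correlated across genes with r = 0.629, against 0.390 in simulated arrays that share the ES lines and have no group difference. The simulation drew the 3 common EC lines as independent arrays, so 0.390 leaves out what these lines add. With the ES lines divided between the comparisons the mean was 0.479 (0.217 to 0.647 over 20 divisions). With different EC lines also it was 0.317 (0.082 to 0.488). The divided comparisons share no array, so 0.390 is no reference for them. Genes are not independent replicates.

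The third comparison asked how feeders in place of plastic alter the same 3 EC lines. No gene passed by limma: 0 of 22011 were higher or lower, with 3276 at an unadjusted p below 0.05 and a smallest adjusted p of 0.12. The genes with the smallest p that were higher on feeders were TNC, a matrix glycoprotein (1.73, adjusted p = 0.169), CRABP2, a retinoic acid binding protein (1.42), SLC25A4 (1.28), the amino acid transporter SLC7A5 (1.92), the mitochondrial gene ND6 (1.54) and GTF3C6 (1.47). Those lower were SLCO4C1 (-1.69), CLEC4D (-2.05), SOCS4 (-1.54), ZNF675 (-2.0), RIF1 (-1.29) and LINC01559 (-1.36), with adjusted p of 0.169 to 0.237 over the 12 genes. CER1 was at 7.44 ± 1.42 on feeders and 5.03 ± 0.44 on plastic in these lines (SD, n = 3; difference 2.42, adjusted p = 0.246). Limma called 0 higher and 11 lower with dim clusters left out (2986 at an unadjusted p below 0.05), 25 and 37 with the spread of all 14 arrays, and 0 and 1 without the line block (1785).

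By list, fibroblast and extracellular matrix genes were higher on feeders, with 28 of 31 above 0 (median 0.51, adjusted p = 4.22e-06; adjusted p = 0.623 with an estimated correlation). Limma called 0 members over all genes and 5 adjusted over the list alone; VIM differed by 1.23 and COL6A1 by 1.06. The list's median was 0.36 in 2102Ep, 0.21 in 833KE and 0.60 in NTERA2. Pluripotency genes were lower on feeders (median -0.27, adjusted p = 0.00154; adjusted p = 0.623 with an estimated correlation), at -0.36, -0.30 and -0.41 in 2102Ep, 833KE and NTERA2, with 0 members called by limma (0 adjusted over the list alone); OTX2 differed by -0.97 and L1TD1 by -0.89. That call was lost with the spread of all 14 arrays (adjusted p = 0.0852). The 12p list was lower by a median of only -0.070 (adjusted p = 0.0156; adjusted p = 0.849 with an estimated correlation), a call lost without NTERA2 (adjusted p = 0.121), with quantile normalisation (0.0678), with the spread of all 14 arrays (0.312) and with the code as a block (0.649); limma called 0 of its 102 members (0 adjusted over the list alone). The 20 other lists did not pass, with WNT genes nearest at an adjusted p of 0.0596. The median and mean differed in sign for germline genes (0.0093 and -0.069), cell cycle genes (0.016 and -0.016) and metallothioneins (-0.0031 and 0.040), whose tests followed the mean. In all, 3 of 23 lists passed with the preset correlation, 0 with an estimated correlation and 0 with fry.

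Whether growth on feeders moved EC lines towards ES levels was asked with genes chosen on other arrays. The 219 genes higher in NCCIT and TERA1 on plastic than in ES were lower on feeders in the 3 other EC lines by a median of -0.32 (unadjusted camera p = 7.07e-13, p = 0.0747 with an estimated correlation, fry p = 0.0313), at -0.30 in 2102Ep, -0.46 in 833KE and -0.18 in NTERA2. The 121 genes lower in NCCIT and TERA1 were higher on feeders by a median of 0.21 (unadjusted camera p = 4.33e-04, p = 0.358 with an estimated correlation, fry p = 0.330), at 0.50 in 2102Ep, 0.065 in 833KE and -0.037 in NTERA2. With later-coded ES arrays alone in the choice, 34 genes gave -0.38 and 37 genes 0.27. In 2102Ep and NTERA2 the feeder arrays have earlier codes and the plastic arrays later ones, so codes and growth condition cannot be told apart there. In 833KE both arrays have later codes.

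At exon level, limma called 5940 probesets higher and 2140 lower in EC on plastic than in ES (8080 of 287329), in 1901 genes; among later-coded arrays the counts were 1750 and 706, and with 1 array left out they ran from 2651 and 1048 without 2102Ep to 7811 higher without H9 and 3569 lower without NTERA2. Exon usage asks which probesets departed from the rest of their gene. A probeset of GATA6 (probeset 3781275) fell by 2.73 more than its gene's other probesets, at 5.27 ± 0.73 in EC (SD, n = 5) against 8.30 ± 0.89 in ES (SD, n = 6; adjusted p = 6.99e-08). Probesets of CLSTN1, a calsyntenin (-2.22), and INPP5F (-2.36, with an SD of 2.93 among EC arrays) were lower than the rest of their gene and one of the kinase LIMK2 (2.18) higher, in genes whose own level was not called. In SLCO4C1 (-2.59), ETV5 (-2.54), STOM (-2.46), TFCP2L1 (-2.45), RASSF8 (-2.20) and VAT1L (2.61) the gene was called and the probeset itself differed by 0.38 or less between the groups. In all 189 probesets in 169 genes were called, 62 higher and 127 lower than the rest of their gene, among 112632 probesets in 6919 genes. The splicing index called 4 probesets, 2 of them shared, and of the 10 genes named here left RASSF8 alone. Among later-coded arrays 109 probesets were called, 75 of them shared; the count was 73, 83 and 110 without 2102Ep, 833KE or Shef5, and 300 and 383 without NCCIT or H9. EC arrays on feeders in place of plastic gave 71 probesets, 17 of them shared. There the GATA6 probeset differed from its gene by -0.85 (adjusted p = 1.00). On feeders this probeset was at 5.69 in 2102Ep and 5.68 in 833KE, below the lowest ES array (7.34). In NTERA2 it was at 8.88 on feeders and 5.72 on plastic, so the smaller difference rests on that line. Of the 8 probesets named here that were measured with EC arrays on feeders, those of CLSTN1 and RASSF8 were called. Those of GATA6, SLCO4C1, ETV5, STOM, INPP5F and LIMK2 were not.

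**Figure D4:**
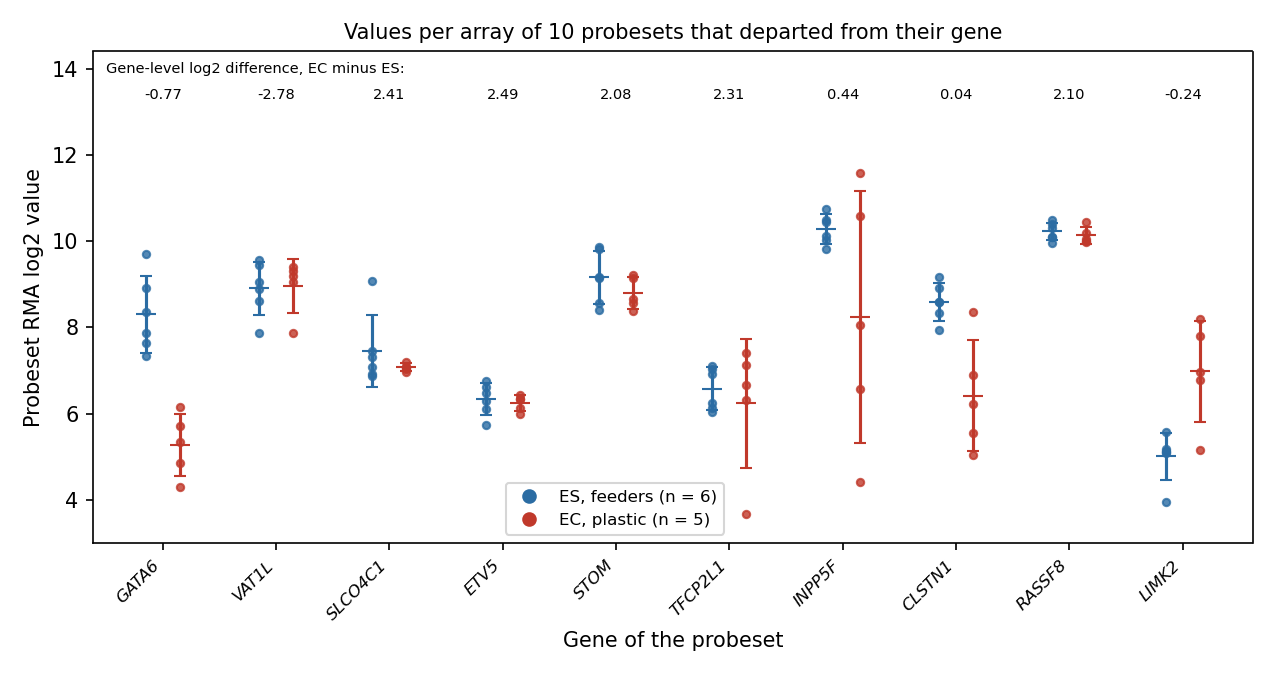
RMA log2 value (y axis) of 10 probesets called for exon usage (x axis, by gene) in each ES array and each EC array on plastic; bars give mean and SD, and the numbers above give the gene-level difference. The CLSTN1 probeset fell while its gene differed by 0.04, and the RASSF8 probeset was at 10.14 in EC and 10.23 in ES while its gene rose by 2.10.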

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

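Chosen only after their results were seen were the tests of the array codes, of RNA of the mouse feeder cells and of probesets that do not follow their gene, the counts of splits for single lists, and the division of chromosome 12 genes by signal.

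Single arrays stood far from the rest of their group in 15 of 308 pairs of a named gene and a group, about the 1 in 20 that chance gives. NCCIT on plastic was apart in 6: STMN2, a neural marker, at 10.23, ADM, a hypoxia target, at 10.78, INHBE at 7.76, CXCR4 at 6.48, RBM24 at 6.43 and CGAS at 5.34, the last lower than in the other EC lines. NTERA2 on plastic was apart in 5, all higher: SFRP1 at 8.31, MGAT4C at 4.21, LEF1 at 4.96, PIWIL1 at 4.43 and BNIP3L at 9.64. TERA1 had the lowest NAP1L5 of the EC lines on plastic at 3.44. Among ES lines H9 was apart in NAP1L5 at 5.48 and STMN2 at 6.99, and Shef5 in CCND2 at 9.40.

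Other splits of the same arrays into groups of the same sizes were counted. For genes in EC on plastic against ES, 1 of 100 splits, the real one, gave 1012 calls and the highest other gave 76, so chance is excluded. For EC on feeders against ES, 1 of 84 gave 504 and the highest other gave 2, so chance is excluded there too. For the number of lists passing it is not: 6 of 100 splits gave 10 or more lists in EC on plastic (highest other 11), and 39 of 84 gave 5 or more in EC on feeders (highest other 11). List by list in EC on plastic, a p as small came from 1 of 100 splits, the real one, for the 12p and endoderm lists, from 4 for the sterol and WNT lists, 5 for fibroblast genes, 6 for FGF response, 9 for pluripotency, 10 for germline, 16 for mesoderm and 20 for neural markers. In EC on feeders it came from 1 of 84 splits for 12p, 5 for splicing regulators, 10 each for endoderm and germline and 13 for neural markers. For probesets 1 of 100 splits gave 8080 calls (highest other 132), which excludes chance. For exon usage 2 of 100 gave 189 or more, a share under 0.05, yet the other split gave 284, more than the real one. It set H14, Shef5, Shef6, Shef7 and NCCIT against the rest, which keeps both earlier-coded arrays on 1 side, as the real split does. This count therefore does not tie the exon usage calls to EC against ES. The cause of the calls in the other split was not tested. Among later-coded arrays exon usage gave 109. For feeders against plastic, exchanging the arrays of 1 line gives 4 splits, too few for a share under 0.05; limma made 0 calls in the real split and 0 in the highest other (4 of 4 gave as many), with 3276 genes at an unadjusted p below 0.05 in the real split and 471, 457 and 1152 in the others.

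The first pattern is the difference between feeders and plastic in EC lines. The array codes may contribute: the gap between earlier- and later-coded ES arrays correlated across genes with feeder minus plastic at 0.565 for NTERA2 and 2102Ep, whose feeder arrays have earlier codes, and at 0.126 for 833KE, whose arrays both have later codes, a difference of 0.439. Growth condition also may: feeder minus plastic in 833KE correlated with the other 2 lines at 0.224, just above the 0.2 set beforehand. RNA of mouse fibroblasts is a further candidate source, although sorting for SSEA3 would remove such cells: COL1A1 (0.51), COL1A2 (0.75), COL3A1 (0.19), SPARC (0.18) and FN1 (0.76) had a median of 0.511, but SPARC was at -1.12 in 833KE, and EC lines on plastic, without feeders, also gave signal for these genes (SPARC 10.05, FN1 7.63). The fibroblast and extracellular matrix list had the same median, 0.511, which is the value of COL1A1 in both. The test of these genes therefore restates that list's rise, and cannot tell mouse RNA from matrix genes expressed by the EC lines. It leaves mouse RNA undecided. The tests of array codes and of growth condition argued against neither of these explanations, and more than 1 of the 3 can hold.

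The second pattern is the higher level of 12p genes in EC lines. The array codes are argued against, since the list's median among later-coded arrays was 0.962 of its value over all arrays. The choice of the listed genes may explain part. Over all genes, 12p genes outside the list reached 0.437 of the listed genes' median, under the 0.5 set beforehand. Among brighter genes alone, divided after the data were seen, the medians were 1.14 outside and 1.32 on the list. In EC on feeders they were 1.32 and 1.33. For the brighter genes these values argue against the choice of the list. A shift of the whole arm remains open as a hypothesis: genes outside the list had a median of 0.482, short of the 0.5 set beforehand, against 0.056 on the long arm. Among brighter genes these medians were 1.14 and 0.15. Copy number, which germ cell tumours are known to gain there, was not measured.

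The third pattern is the 189 probesets called for exon usage. Probesets that do not follow their gene's level could account for some. Of all 189, 39.2% lay in genes called at gene level and differed by less than 0.5 of the gene's difference. That share lay between the bounds of 20 and 50 set for the test. Of the 111 called probesets in such genes 74 did so, against 806 of 7627 kept probesets of such genes. A probeset is called for departing from its gene, so a higher share among called ones is partly built in. Signal near background could account for others: in the lower of both groups, called probesets lay -0.969 from uncalled ones, short of the 1 log2 unit set beforehand. A called probeset must depart from its gene by at least 1, which can itself pull down the lower of its group means. This value therefore cannot tell signal near background from the calling rule. Neither explanation can be told apart from exon use that differs between EC and ES lines, since both values fell between their bounds. That biological explanation was not tested.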

How the results depend on the processing

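All alternatives that use the array codes were chosen after seeing the data; the others were planned. No called named gene changed sign under any alternative; calls lost per gene are given as counts. For EC on plastic against ES (718 higher, 294 lower), counts fell beyond 1.5 times with a 2-fold minimum (406 and 159, by construction) and among later-coded arrays (376 and 151, with fewer samples). Leaving out 1 array gave 416 to 853 higher, 167 to 428 lower and 9 to 13 lists; Shef3 (416 and 171), 2102Ep (437 and 167), Shef7 (422 higher), Shef6 (444 and 190), H14 (475 and 181), 833KE (177 lower) and TERA1 (182 lower) moved counts that far. Lists passing fell from 10 to 0 with an estimated correlation. Of 63 called named genes, 49 were still called among later-coded arrays, 56 with the code as a block, 59 with quantile normalisation, 48 with the 3 lines also grown on feeders and 51 to 61 with 1 array left out. For EC on feeders against ES (343 and 161), lower genes were 243 with quantile normalisation and 103 with the spread of all 14 arrays. Higher genes were 186 among later-coded arrays, and limma called 0 and 0 among earlier-coded ones (2 against 2 arrays, 2366 at an unadjusted p below 0.05). Leaving out 1 array gave 123 to 385, 44 to 229 and 4 to 10 lists; Shef3 (123 and 44), 2102Ep (126 and 67), Shef6 (172 and 63), Shef7 (171 and 89) and 833KE (71 lower) moved the gene counts, and NTERA2 (10) and 2102Ep (8) the lists. Lists were 0 with an estimated correlation, 2 with fry and 10 among later-coded arrays. The germline list's median was -0.076 with dim clusters left out, which removes members of the list. Of 49 called named genes 41 were called with the code as a block, 27 among later-coded arrays and 22 to 47 with 1 array left out. For feeders against plastic (0 and 0), limma called 11 lower with dim clusters left out, 25 higher and 37 lower with the spread of all 14 arrays and 1 lower without the line block; lists were 0 with an estimated correlation, 0 with fry and 1 with the spread of all 14 arrays, and 4 to 6 without 1 line (5 without NTERA2, 6 without 2102Ep). The first principal component held 36.5% over the 1000 most variable clusters and 18.6% at unit variance. Chromosome 16 had a median of 0.14 in EC on feeders. Probesets (5940 and 2140) were 1750 and 706 among later-coded arrays, and 2651 to 7811 and 1048 to 3569 with 1 array left out (beyond 1.5 times without 2102Ep at 2651 and 1048, H14 at 3408 and 1141, Shef3 at 3218 and 1207, 833KE at 3241 and 1109, Shef6 at 3570 and 1303, Shef7 at 3325 and 1426, Shef5 at 3542 higher, TERA1 at 1309 lower and NTERA2 at 3569 lower). Exon usage (189 probesets, 169 genes) was 4 and 4 with a splicing index, 844 and 683 without the filter, 108 and 101 with a filter at the median, 71 and 62 with EC arrays on feeders, 109 and 98 among later-coded arrays, and 73 to 383 and 68 to 329 with 1 array left out (2102Ep 73, 833KE 83, Shef5 110, NCCIT 300, H9 383; genes also without Shef7, 111). Except where the construction is named, the cause was not tested. Without detection p-values, signal over background limits the reading of dim clusters and probesets.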

Other observations

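Zinc finger genes with ZNF symbols, collected after ZNF208, ZNF560, ZNF99 and ZNF680 were seen among the largest gains, were called higher in EC on plastic than in ES in 19 of 125 on chromosome 19 and lower in 1 (median 0.31). On other chromosomes 22 of 159 were higher and 2 lower (median 0.24). The 823 other genes of chromosome 19 had 2 higher and 24 lower (median -0.11). In EC on feeders against ES the counts were 3 higher and 1 lower of the 125, with a median of -0.044, and 4 and 0 of the 159, with a median of 0.084; the difference between the growth conditions was not tested for this group.

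Over the 115 brighter of 256 genes of chromosome 13, relative to the median of all brighter genes of each array, 5 EC arrays were lower than the ES lines, which lay between -0.12 and 0.10. The medians were -0.81 on plastic and -0.86 on feeders in 2102Ep, -0.25 and -0.37 in 833KE, and -0.29 in NTERA2 on feeders. NTERA2 and NCCIT on plastic were within the range of the ES lines, at -0.013 and -0.060, and TERA1 was above it, at 0.14. This chromosome was chosen after its values were seen. Over all its genes the median difference was -0.22 in EC on feeders against ES, with the smallest camera p of any chromosome (adjusted p = 1.34e-12; adjusted p = 0.194 with an estimated correlation), and -0.050 in EC on plastic (adjusted p = 0.0510; 0.822 with an estimated correlation). In 14 of the genes with a probeset called for exon usage, the probeset's own level was called while the gene's was not, also chosen after their values were seen. Among them the probeset of GNAS, which encodes a G protein subunit, differed by -2.21 and that of SPAG9 by -1.99, while those of ONECUT1, a transcription factor, FGF4, a growth factor, and BARX1 were higher by 2.13, 2.29 and 1.88. The gene-level differences of these 5 lay between -0.40 and 0.84. Their gene-level adjusted p by limma ran from 0.0501 in FGF4 to 0.513 in SPAG9. FGF4, whose gene differed by 0.84, thus missed the threshold only narrowly. Between ES arrays with earlier and later codes (2 against 4) limma called 0 genes. Yet 4476 lay at an unadjusted p below 0.05, against 4233 for EC on plastic against ES and 3875 for EC on feeders against ES. The 0 calls therefore do not show that the codes matter little.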
